A study of Rattus norvegicus with 24 samples.

How the data were processed

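Affymetrix arrays were hybridised with RNA of the supraoptic nucleus, each array with a pool of 5 Sprague Dawley rats. Per the labels, male rats were 10 to 12 weeks old. The male samples were extracted with QIAzol and RNeasy and amplified with an Ambion kit, and the female samples were extracted with Trizol and labelled with Affymetrix reagents. The deposited values are intensity signals per probe set, which the authors made with GCOS 1.2 for the male arrays and with MAS5 for the female arrays, and scaled so that the 2% trimmed mean of each array is about 100; they are not log transformed. The background correction and probe summary settings are not stated in the labels. Scanner files, detection calls and scan dates were not used here. The design text says that the pooled samples of a group may count as both biological and technical replicates, so the spread between arrays is that between pools and need not be that between rats.

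Of 24 samples, 19 had values: 4 control females, 5 dehydrated females, 5 control males and 5 dehydrated males. The columns of the 5 lactating samples were empty in the table used, so the comparisons planned with that group were not analysed here. No pair of arrays held identical values. Each array was rescaled to a trimmed mean of 500 and transformed as log2(value + 32). The 57 control probe sets were left out, and probe sets were kept whose mean log2 value over the arrays of a fit was above the 30th percentile, which left 21729 of 31099 in each fit. Signals printed as levels are the deposited ones. Probe sets were matched to gene symbols by the annotation of the platform, with symbols updated by Entrez ID: 20832 had a single symbol, 436 several and 9831 none. No genome sequence was used, so no positions are given. The number of arrays limits the precision: the median SE of a log2 fold change was 0.24 in females, 0.17 in females without array 5 and 0.12 in males.

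Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05 on the adjusted p. Female dehydration was fitted on the female arrays and male dehydration on the male arrays. The difference between the dehydration effects was fitted on all arrays; each set has its own controls, but sex, extraction and labelling change together. Fold changes are dehydrated over control on the log2 scale, with standard errors from the moderated fit. The overlap of the sets was tested per direction with a 1-sided Fisher's exact test over probe sets tested in both. Array measures (3' to 5' ratios of control probe sets and mean marker values) were compared between groups with 2-sided exact permutation tests. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

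Before the data were examined, 17 gene lists, 11 cell type marker lists, the comparisons, the alternatives and a rule for named genes were fixed. The gene lists were magnocellular neuropeptides, dense core granule and peptide processing, ER chaperones and unfolded protein response, ER translocation and vesicle traffic, amino acid supply and ATF4 response, activity-regulated and immediate early genes, cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosomal proteins, heat shock response, proteasome, hormone receptors and prolactin signalling, channels and transporters of excitability and osmosensing, GABA and glutamate receptors, structural remodelling and extracellular matrix, and cell cycle. The marker lists were astrocyte, oligodendrocyte and myelin, microglia and macrophage, endothelium, mural cell and meninges, blood, ependyma and choroid plexus, GABAergic neuron, cortical and amygdalar neuron, other hypothalamic neuron, and magnocellular neuron. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists of a comparison, and repeated with camera's estimated correlation and with fry. fry tests whether a list's genes move on balance in a single direction and does not compare them with other genes. A list is called higher or lower by camera at an adjusted p under 0.05. A gene was represented by its probe set with the highest mean among those with a single symbol.

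The named genes were the 10 largest rises and 10 largest falls per dehydration comparison (6 each for the difference between sets) past the threshold and above the median level of the probe sets kept, up to 2 rising and 2 falling members per list or, where none passed, the member with the smallest p, Avp and Oxt, and Xist with Y-linked genes as a check of the sex labels. Symbols that are locus names were not ranked. Of the genes that met the rule, 1 is not reported here. Genes named outside that rule are marked as chosen after their values were seen.

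Alternatives planned before the data were examined were quantile normalization, centring arrays on their median, and offsets of 1 and 100. No filter, a filter at the 50th percentile, array weights and no mean-variance trend were planned too. So were all groups in 1 fit for males and leaving out each array. For lists an estimated correlation, fry and the mean over a gene's probe sets were planned, and for the overlap a threshold of 0.01. After the data were seen, array 5 (dehydrated female replicate 5) was left out as a further analysis with the same alternatives. The fit of all groups for females and median centring for the lists were then added. The beta-actin 3' to 5' ratio and the mean of the meninges markers were each added as a covariate. The fits were tested on simulated data, drawn for each probe set from its mean and residual SD with known changes added, so that correlation between probe sets was not simulated. At a simulated log2 change of 1, limma recovered 30% of the changed probe sets in the female fit, 64% without array 5 and 90% in the male fit. Of the calls 7.35%, 3.28% and 5.20% were false. The simulated noise was spread evenly over the arrays, and each change was added to every dehydrated array. The 30% therefore does not measure what a fit can find when 1 array stands apart, as array 5 did. Up to 100 splits of the arrays, the real one included, were fitted for each count of calls.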

Results

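The data were expression values of the rat supraoptic nucleus, the hypothalamic nucleus whose magnocellular neurons make vasopressin and oxytocin for release from the posterior pituitary. Each Affymetrix array held RNA pooled from 5 Sprague Dawley rats, and gave a signal for 31099 probe sets. Values were analysed for 19 arrays: 4 of control females, 5 of females deprived of water for 72 hours, 5 of control males and 5 of males deprived of water for 3 days. The 5 arrays of rats on day 11 of lactation had no values in the table used here, so the lactating state was not analysed here. Signals had been scaled to a trimmed mean of about 100 on every array, and the median signal per array ran from 36.1 to 64.4. The number of arrays limits the precision of every value below.

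Avp and Oxt, the genes of vasopressin and oxytocin, were among the strongest signals on 18 of the 19 arrays. Avp signal lay between 3644 and 7666 on 8 of the 9 female arrays and between 4337 and 5928 on the male arrays. Oxt signal lay between 3001 and 6698 on the same 8 female arrays and between 3872 and 5572 on the male arrays. The array labelled dehydrated female replicate 5, called array 5 below, gave an Avp signal of 50.6 and an Oxt signal of 26.0. Xist, the RNA that silences an X chromosome in female cells, read 2.59 on array 5, 461.9 to 693.6 on the other female arrays and 0.40 to 8.0 on the male arrays. The Y-linked gene Eif2s3y read 242 on array 5, 0.10 to 8.94 on the other female arrays and 252 to 391.3 on the male arrays. The mean log2 value of the endothelium markers was 1.96 higher on array 5 than the mean of the other 8 female arrays, that of the blood markers 2.01 higher and that of the oligodendrocyte markers 1.77 higher. Ttr, the transthyretin gene of the choroid plexus, read 9458 on array 5 against 673 ± 494 (SD, n = 8). Array 5 correlated across probe sets with the other female arrays at a median r of 0.717, while pairs of the others lay between 0.910 and 0.972; probe sets are not independent replicates. Female results are therefore given with all 9 arrays, as planned, and without array 5. Leaving out each array in turn was planned, and singling out this one was a choice made after the values were seen.

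**Figure D1:**
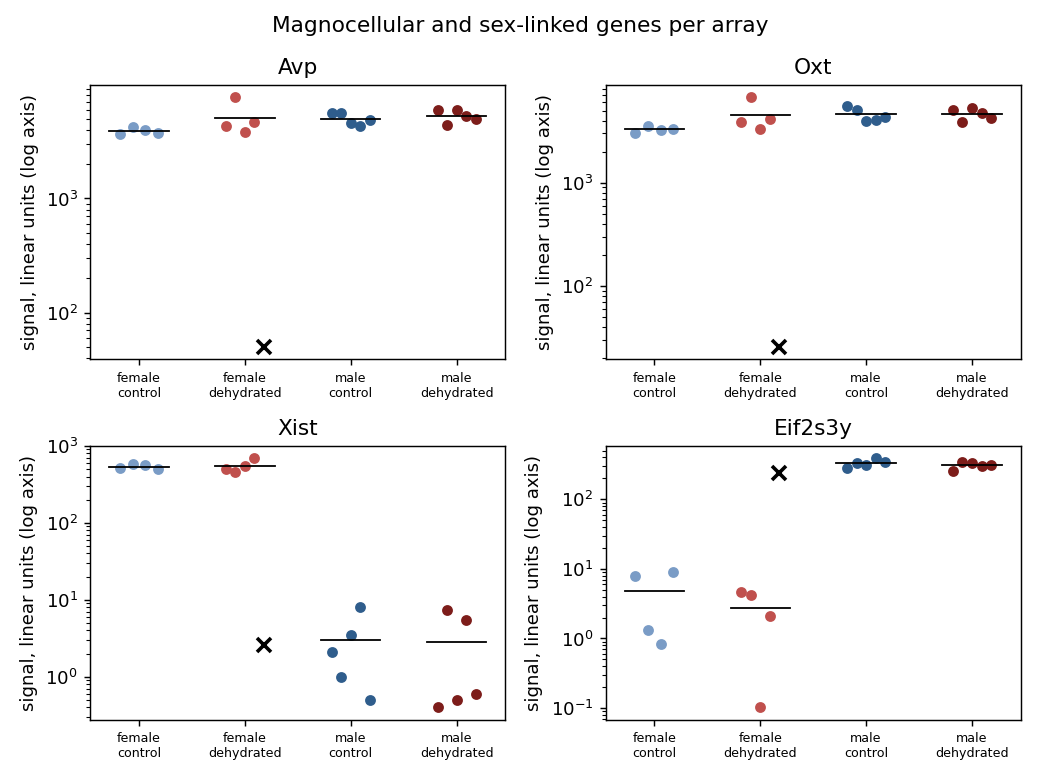
Signal (log axes, linear signal units with a trimmed mean of about 100) of Avp, Oxt, Xist and Eif2s3y on each of the 19 arrays, by group, with points for arrays, lines for group means without array 5 and a cross for array 5. The cross lies at 2.59 for Xist and at 242 for Eif2s3y, nearer the male than the other female arrays, and at 50.6 for Avp.

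The first comparison asked which transcripts of the female nucleus change with 72 hours of water deprivation. Crh, which encodes corticotropin-releasing hormone (probe set 1369303_at), rose by 2.94 ± 0.24 on the log2 scale (SE, n = 5 against 4; limma adjusted p = 0.00156) with all arrays, and was the only probe set of 21729 past the threshold. Its signal was 36.5 ± 3.71 (SD, n = 4) in controls and 378 ± 30.5 in the 4 other dehydrated arrays, with 172 on array 5. At an unadjusted p under 0.05 there were 1785 probe sets, where 1086 were expected by chance. Without array 5, 643 probe sets passed, 384 higher and 259 lower, of which 94 rises and 27 falls were beyond 2-fold; they covered 435 genes. That count ran from 210 to 886 as each of the 8 arrays was left out, and 6 of the 8 gave 210 to 346. In 1 fit with all 4 groups 2322 passed. The 384 rises and 259 falls became 348 and 114 when arrays were centred on their median, a shift of 0.04 in the median log2 fold change.

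Without array 5, the largest rise of the named genes in dehydrated females was that of Dpys (1387284_at), dihydropyrimidinase of pyrimidine breakdown. Its signal went from 16.8 ± 8.71 to 371 ± 111 (SD, n = 4 each), a log2 fold change of 4.06 ± 0.29. Its control signal is low, and the size and rank of its rise depend on the value added before the log2 transform. Tnfaip6 (1371194_at), a hyaluronan-binding secreted protein, rose from 55.9 ± 7.95 to 818 ± 118, a log2 fold change of 3.72 ± 0.14. Crh rose by 3.16 ± 0.12, Oacyl by 3.19 ± 0.21, the zinc finger gene Giot1 by 2.85 ± 0.19 and the opsin Opn3 by 2.61 ± 0.15. Th, the rate-limiting enzyme of catecholamine synthesis, rose 3.95-fold, and the immediate early gene Fos rose 3.67-fold. Vgf, the precursor of several secretory granule peptides, rose 3.28-fold. The adjusted p of these 9 genes ran from 4.7e-08 for Crh and Tnfaip6 to 0.0012 for Fos.

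Among the genes ranked by the rule for named genes, the largest falls in dehydrated females without array 5 were smaller than the rises. Probe sets without a single symbol or at lower levels were not ranked. Igfbp5 (1370960_at), a binding protein of insulin-like growth factors, had a log2 fold change of -1.16 ± 0.16 (n = 4 each; limma adjusted p = 0.00386), and Igfbp2, another of them, of -0.91 ± 0.19. The myelin genes Opalin, Bcas1 and Mag fell by 1.10 ± 0.27, 0.95 ± 0.18 and 0.92 ± 0.15. The collagen gene Col1a2 fell by 1.01 ± 0.15, the sulfate transporter Slc13a4 by 0.98 ± 0.17 and Cdkn1c, an inhibitor of cyclin-dependent kinases, by 0.93 ± 0.21. Dbp, a transcription factor with a daily rhythm, fell by 0.99 ± 0.22, and Lin7b fell by 0.94 ± 0.16. With all 9 arrays none of these falls passed limma's threshold. On the arrays used without array 5, 4 of 15 mural cell and meninges markers fell. With the mean of those markers as a covariate 6 probe sets passed, all of them rises. The median log2 fold change of the 27 falls beyond 2-fold went from -1.15 to -1.20 and their median SE from 0.242 to 0.502. Igfbp2 went to 0.0512, but it is itself one of those markers, so its shrinking is in part by construction. The markers' mean ran from 10.00 to 10.31 on the control arrays and from 9.59 to 9.88 on the dehydrated arrays used. The covariate can therefore hardly be told apart from dehydration itself.

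**Figure D2:**
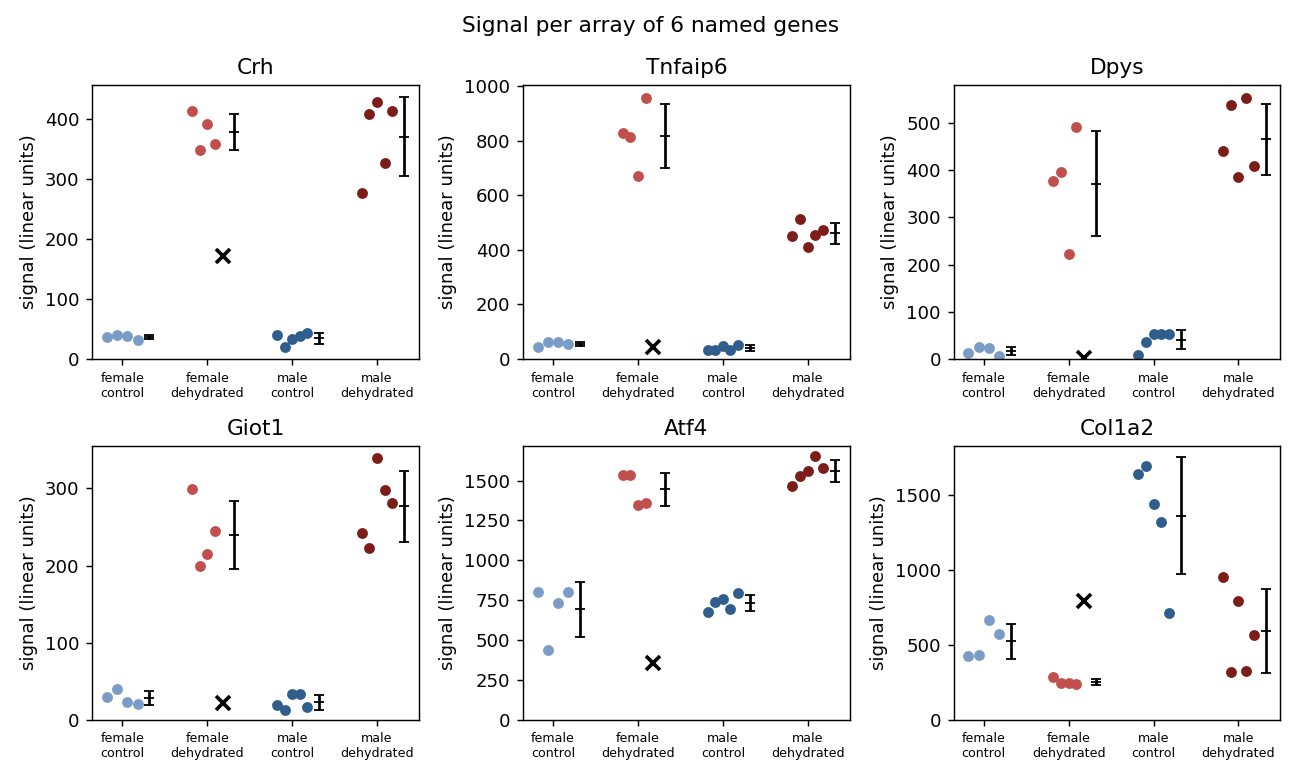
Signal (linear axes from 0, units with a trimmed mean of about 100) of Crh, Tnfaip6, Dpys, Giot1, Atf4 and Col1a2 on each array, by group, with points for arrays, bars for the group mean and SD without array 5, and a cross for array 5. Crh averages 36.5 in control and 378 in dehydrated females and 34.4 and 370 in control and dehydrated males, with 172 on array 5.

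Among the gene lists, genes of amino acid supply and the ATF4 response moved up in females without array 5. Of 35 measured members 12 rose and none fell over all genes tested, and 21 rose when adjusted over the list alone (camera adjusted p = 1.2e-10; adjusted p = 0.0459 with an estimated correlation). Atf4 itself, a transcription factor of the integrated stress response, rose by 1.09 ± 0.18 (n = 4 each), and Mthfd2, a mitochondrial folate enzyme, by 1.63 ± 0.25. Of 25 activity-regulated and immediate early genes 7 rose and none fell, and 11 rose adjusted over the list alone (adjusted p = 0.0459 with an estimated correlation). The latter list also moved up with all 9 arrays, with a mean log2 fold change of 0.51 over 24 members, 0 of them past limma's threshold over all genes, 7 higher at an unadjusted p under 0.05 and 4 adjusted over the list alone (adjusted p = 0.00821 with an estimated correlation). These were the only lists whose call held in females with an estimated correlation.

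Secretory pathway lists, among others, moved up in the same female comparison by camera's preset correlation and lost that call with an estimated correlation. Of 27 dense core granule and peptide processing genes 2 rose, Vgf and the secretogranin Scg2 (1.09 ± 0.13), and none fell; adjusted over the list alone 5 rose and 1 fell (adjusted p = 0.0613 with an estimated correlation). Of 35 ER chaperone and unfolded protein response genes 4 rose, among them Creb3l1, an ER-anchored transcription factor (1.31 ± 0.14), and Ddit3, a transcription factor of ER stress (0.70 ± 0.16); 8 rose adjusted over the list alone (adjusted p = 0.0684 with an estimated correlation). Of 48 genes of ER translocation and vesicle traffic 1 rose, Tmed10 (0.64 ± 0.10), and 3 adjusted over the list alone (adjusted p = 0.0613 with an estimated correlation). Of 21 cholesterol synthesis genes 1 rose, Acat2 (0.52 ± 0.13), and 1 adjusted over the list alone (adjusted p = 0.393 with an estimated correlation). The proteasome list had a mean log2 fold change of 0.26 over 28 members, 0 of them past limma's threshold over all genes or adjusted over the list alone and 10 higher at an unadjusted p under 0.05 (adjusted p = 0.213 with an estimated correlation). The oxidative phosphorylation list had a mean of 0.13 over 41 members, 0 past limma's threshold either way and 2 higher and 1 lower at an unadjusted p under 0.05 (adjusted p = 0.635 with an estimated correlation; the call was lost under quantile normalization). The cell cycle list had a mean of 0.20 over 18 members, 0 past limma's threshold over all genes, 4 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone (adjusted p = 0.189 with an estimated correlation).

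Marker lists of 6 cell types or tissues were called lower, and 1 higher, in the dehydrated females without array 5 by camera's preset correlation. None was called with an estimated correlation. As mean values per array, none of the 11 marker lists passed (2-sided exact permutation test, smallest Benjamini-Hochberg adjusted p = 0.0929). The lowest p that test can give on these arrays before adjustment is 0.0286. After adjustment a list could not pass alone, however clear its shift, so this test cannot decide on single lists. Of 15 oligodendrocyte and myelin markers 5 fell and none rose, and 11 fell adjusted over the list alone, with a mean log2 fold change of -0.59 (camera adjusted p = 5.3e-07; adjusted p = 0.213 with an estimated correlation). Of 15 mural cell and meninges markers 4 fell, Col1a2, Igfbp2 and 2 others, with a mean of -0.39; adjusted over the list alone 10 fell and 1 rose (adjusted p = 0.146 with an estimated correlation). Microglia and macrophage markers had a mean of -0.32 with 0 of 15 past limma's threshold, 6 lower at an unadjusted p under 0.05 and 5 adjusted over the list alone (adjusted p = 0.213 with an estimated correlation). Of 16 astrocyte markers 1 fell, the gap junction gene Gjb6 (-0.76 ± 0.16), and 3 adjusted over the list alone (adjusted p = 0.213 with an estimated correlation). Of 3 blood markers 1 fell, the heme synthesis enzyme Alas2 (-0.88 ± 0.20), over all genes and adjusted over the list alone (adjusted p = 0.213 with an estimated correlation). The 4 GABAergic neuron markers had a mean of -0.34, 0 past limma's threshold, and 3 lower both at an unadjusted p under 0.05 and adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). Of 8 magnocellular neuron markers 1 rose, Calb2, which encodes calretinin (0.87 ± 0.11), and adjusted over the list alone 2 rose and 1 fell; the list's mean was 0.28 (adjusted p = 0.12 with an estimated correlation), and its call was lost under quantile normalization. Without array 5, 16 of the 28 lists were called, 10 higher and 6 lower, and fry called 14 of them too. With all 9 arrays camera called 6, all higher. Besides the immediate early genes these were the ATF4 list (mean 0.24; adjusted p = 0.293 with an estimated correlation), the ER chaperone list (0.16; adjusted p = 0.0995 with an estimated correlation), the cholesterol synthesis list (0.19; adjusted p = 0.293 with an estimated correlation), the cell cycle list (0.33; adjusted p = 0.0995 with an estimated correlation) and the endothelium list (0.42; adjusted p = 0.841 with an estimated correlation). Of their members limma called 0 over all genes; at an unadjusted p under 0.05 there were 4, 6, 4, 5 and 0 higher, and adjusted over the list alone 0, 1, 0, 2 and 0. The endothelium markers were among those higher on array 5, and without it that list was not called (mean 0.03; adjusted p = 0.601).

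The second comparison asked the same of males after 3 days of water deprivation, with 5 arrays per group. Dpys rose from a signal of 40.6 ± 19.9 to 465 ± 75.8 (SD, n = 5 each), a log2 fold change of 3.48 ± 0.31. Tnfaip6 rose by 3.37 ± 0.13, Giot1 by 3.32 ± 0.19, Crh by 3.22 ± 0.16, Procr, the receptor of protein C (1372729_at), by 2.51 ± 0.13 and Opn3 by 2.48 ± 0.14. Oacyl rose 4.21-fold, Fos 3.82-fold, Creb3l1 3.64-fold and Vgf 3.33-fold; adjusted p ran from 7.3e-10 for Tnfaip6 to 7.4e-06 for Fos. By limma 3846 probe sets of 21729 passed the threshold, 1808 higher and 2038 lower, and 68 rises and 102 falls were beyond 2-fold. They covered 2432 genes. The split between rises and falls went to 2710 and 1091 when arrays were centred on their median, a shift of 0.08 in the median log2 fold change. In 1 fit with all 4 groups 427 passed, and 2270 when array 5 was left out of it.

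Slc47a1, an organic cation exporter (1390835_at), had the largest fall of the named genes in males. It fell from 180 ± 105 to 45.2 ± 24.6 (SD, n = 5 each), a log2 fold change of -1.81 ± 0.37 with limma adjusted p = 0.0043. Crabp2, which binds retinoic acid, had a log2 fold change of -1.59 ± 0.30, the dicarboxylate transporter Slc13a3 of -1.55 ± 0.36, the troponin gene Tnnt2 of -1.48 ± 0.34, Slc13a4 of -1.48 ± 0.33 and Plac8 of -1.45 ± 0.18. The matrix gene Efemp1 fell by 1.42 ± 0.19, the GABA transporter Slc6a13 by 1.37 ± 0.30, the organic anion transporter Slc22a8 by 1.35 ± 0.28 and Mpzl2 by 1.32 ± 0.29. On the same arrays, 12 of 15 mural cell and meninges markers fell. With the mean of those markers as a covariate, the median log2 fold change of the 102 falls beyond 2-fold went from -1.17 to -0.41. Of these falls 17 passed. The median of the 68 rises went from 1.22 to 1.28, and 62 passed. The markers that fell, Slc6a13 among them, themselves make up the covariate, so part of the shrinking of the falls is by construction. How many of the 102 falls are such markers was not counted.

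**Figure D3:**
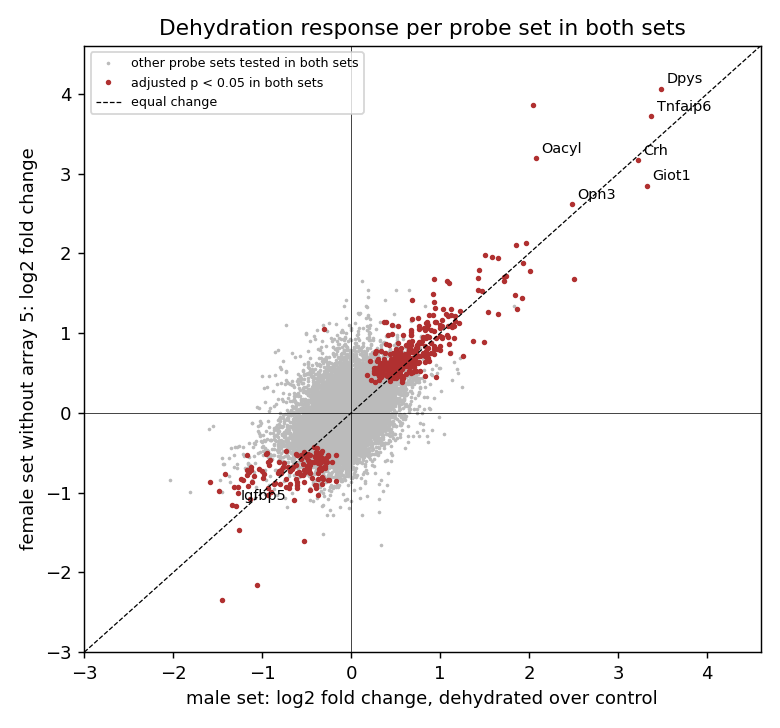
Log2 fold change of dehydrated over control for each of 20492 probe sets, males on the horizontal axis and females without array 5 on the vertical axis, with red points for those past the threshold in both sets and a dashed line for equal change. Of the red points 321 are higher and 139 lower in both sets and 1 lies in opposite directions.

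Genes of amino acid supply and the ATF4 response formed the list with the smallest p in males. Of 36 measured members 24 rose and 3 fell, and 25 rose and 3 fell adjusted over the list alone (camera adjusted p = 2.4e-13; adjusted p = 0.0278 with an estimated correlation). Atf4 rose by 1.09 ± 0.05 (n = 5 each). Chac1, which breaks down glutathione, rose by 1.26 ± 0.08, and the transcription factor Cebpb rose 2.30-fold. Among the 3 that fell, the stress gene Nupr1 had a log2 fold change of -1.29 ± 0.32, and the cystine transporter Slc7a11 of -0.66 ± 0.15. This was the only list of 28 called in males with an estimated correlation.

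The other male lists called higher were lost with an estimated correlation. By fry, which does not compare a list with other genes, 15 of the 16 lists called in males were called too. Of 28 proteasome genes 17 rose and none fell, by 0.39 ± 0.08 for Psmc6, and 22 rose adjusted over the list alone (adjusted p = 0.183 with an estimated correlation). Of 48 genes of ER translocation and vesicle traffic 17 rose and 1 fell, Kdelr3 (-0.65 ± 0.20; 0.0150 with the mean of the meninges markers as a covariate), against 18 and 1 adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). Of 35 ER chaperone genes 12 rose and 3 fell, against 13 and 4 adjusted over the list alone (adjusted p = 0.183 with an estimated correlation). Of 27 dense core granule genes 11 rose and 2 fell, Rab3b (-0.42 ± 0.10) and Chgb (-0.21 ± 0.07), against 11 and 4 adjusted over the list alone (adjusted p = 0.183 with an estimated correlation). Of 27 immediate early genes 8 rose and 1 fell, Ier3 (-0.97 ± 0.24), against 11 and 1 adjusted over the list alone (adjusted p = 0.183 with an estimated correlation). Of 21 cholesterol synthesis genes 7 rose, Acat2 by 0.78 ± 0.09 and squalene epoxidase, Sqle, by 0.53 ± 0.06, and 7 adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). Of 41 oxidative phosphorylation genes 10 rose, Atp5f1d by 0.41 ± 0.06, and 11 adjusted over the list alone (adjusted p = 0.236 with an estimated correlation). Of 19 cytosolic heat shock genes 8 rose, among them the heme oxygenase Hmox1 (0.72 ± 0.10), and 8 adjusted over the list alone (adjusted p = 0.183 with an estimated correlation). The calls of the last 2 lists were lost under quantile normalization.

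Channels and transporters of excitability and osmosensing also moved up in males, with 10 of 35 members higher and 2 lower over all genes, and 12 and 6 adjusted over the list alone (adjusted p = 0.236 with an estimated correlation; the call was lost under quantile normalization). Kcnn3, a calcium-activated potassium channel (1368626_at), rose by 1.85 ± 0.13 in males (n = 5 each) and by 2.10 ± 0.40 in females without array 5 (n = 4 each). Slc12a1, a sodium, potassium and chloride cotransporter, rose by 1.65 ± 0.16 in males and by 1.94 ± 0.19 in those females. The urea transporter Slc14a1 (-0.51 ± 0.11) and the chloride channel Ano1 (-0.47 ± 0.15) fell in males. The list was not called in females without array 5 (camera adjusted p = 0.67), with 2 of 35 higher and none lower, and 2 and 2 adjusted over the list alone.

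**Figure D4:**
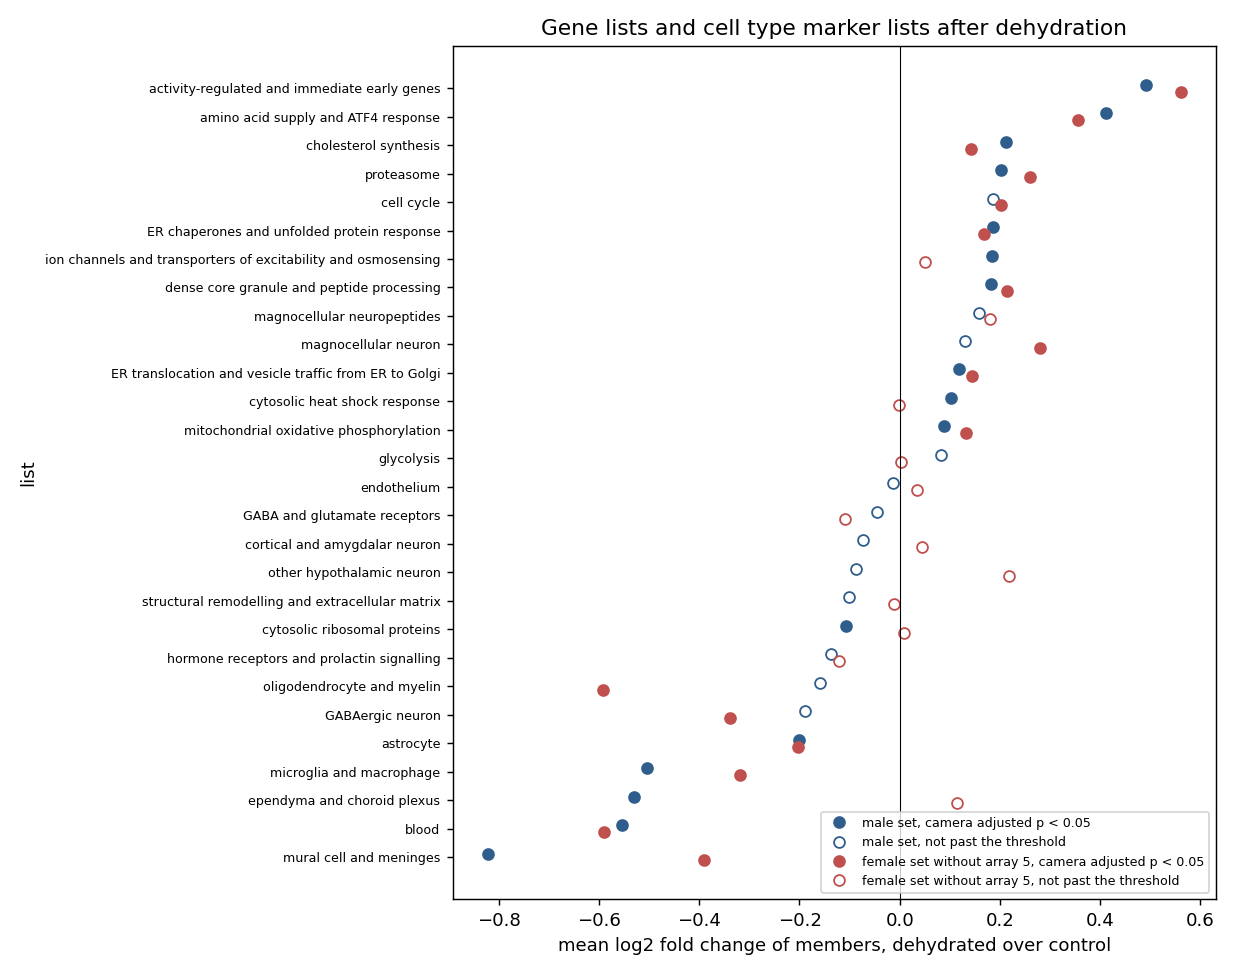
Mean log2 fold change (horizontal axis) of the measured members of each of the 28 gene and marker lists, in blue for males and in red for females without array 5; filled marks are lists called by camera with its preset correlation and open marks lists not called. Amino acid supply and ATF4 genes average 0.36 in those females and 0.41 in males, and mural cell and meninges markers -0.39 and -0.82.

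The ribosomal protein list and 5 marker lists were called lower in dehydrated males by camera's preset correlation, and none with an estimated correlation. As mean values per array, none of the 11 marker lists passed (2-sided exact permutation test, smallest Benjamini-Hochberg adjusted p = 0.0825). The lowest p that test can give on these arrays before adjustment is 0.0079. After adjustment over 13 array measures a list could not pass alone, however clear its shift, so this test cannot decide on single lists. Of 30 cytosolic ribosomal protein genes 9 fell and none rose, Rpl21 by 0.33 ± 0.06 (n = 5 each), and 13 fell adjusted over the list alone (adjusted p = 0.407 with an estimated correlation). The mural cell and meninges list had a mean log2 fold change of -0.82, with 12 of 15 lower and 1, the pericyte gene Rgs5, higher by 0.60 ± 0.10, over all genes and adjusted over the list alone (adjusted p = 0.34 with an estimated correlation). Of 14 microglia and macrophage markers 8 fell, Laptm5 by 0.93 ± 0.16 and the lysozyme Lyz2 by 0.81 ± 0.21, and 11 adjusted over the list alone (adjusted p = 0.236 with an estimated correlation). Of 16 astrocyte markers 6 fell, Gjb6 by 0.82 ± 0.19 and vimentin, Vim, by 0.60 ± 0.18 (0.0904 with the mean of the meninges markers as a covariate), and 10 adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). Of 7 ependyma and choroid plexus markers 3 fell, Ttr by 0.85 ± 0.17 and Rarres2 by 0.97 ± 0.25, and 3 adjusted over the list alone (adjusted p = 0.349 with an estimated correlation). Of 3 blood markers 2 fell, Hbb by 0.97 ± 0.10 and Alas2 by 0.86 ± 0.17, and 2 adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). The beta-actin 3' to 5' ratio, a sign of RNA quality, was 7.92 ± 0.78 (SD, n = 5) in dehydrated and 6.35 ± 0.80 in control males (2-sided exact permutation p = 0.0238; 0.0825 after Benjamini-Hochberg adjustment over 13 array measures). With that ratio as a covariate 1540 probe sets passed, while the median log2 fold change of the 68 rises beyond 2-fold went from 1.22 to 1.41 and that of the 102 falls from -1.17 to -1.47, and their median SE from 0.137 to 0.202 and from 0.254 to 0.369.

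**Figure D5:**
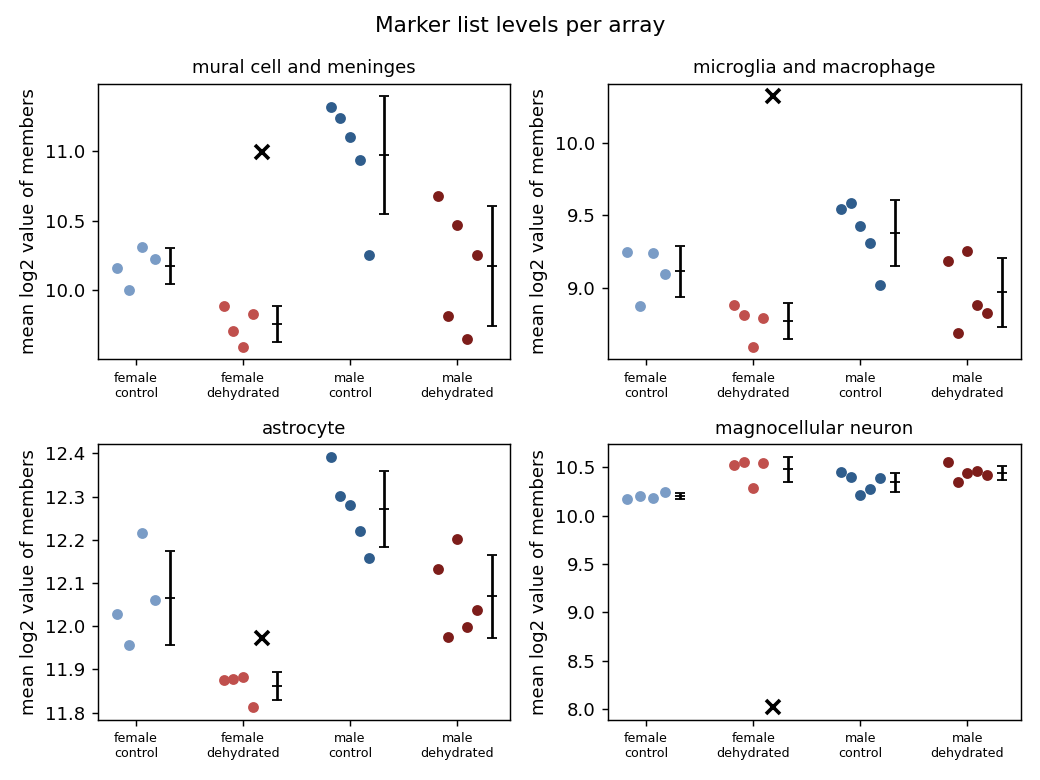
Mean log2 value of the members of 4 marker lists on each array, by group, with points for arrays, bars for the group mean and SD without array 5, and a cross for array 5. The mural cell and meninges value averages 10.97 in control and 10.17 in dehydrated males, and the magnocellular neuron value is 8.02 on array 5.

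Avp and Oxt, the products of the nucleus, did not pass the threshold in either set. By signal Avp ranked 1 to 6 and Oxt 5 to 14 on the male arrays. On the female arrays without array 5 they ranked 2 to 13 and 7 to 47. Whether signals so near the top of the range understate a change was not tested. In males the log2 fold change was 0.08 ± 0.09 for Avp and 0.02 ± 0.10 for Oxt (n = 5 each; limma adjusted p = 0.563 and adjusted p = 0.915). In females without array 5 the values were 0.33 ± 0.19 and 0.40 ± 0.19 (n = 4 each; limma adjusted p = 0.38 and adjusted p = 0.283), and with all arrays -0.95 ± 1.18 and -1.01 ± 1.29. Pdyn, the precursor of dynorphins, rose by 0.87 ± 0.12 in males and by 0.74 ± 0.12 in females without array 5. Of 17 neuropeptide genes of magnocellular neurons in males 2 rose, Crh and Pdyn, and 2 fell, Npff (-0.44 ± 0.13) and Cartpt (-0.34 ± 0.10), and the same numbers adjusted over the list alone; the list was not called (camera adjusted p = 0.769). In females without array 5, 2 of 18 rose and none fell, against 2 and 2 adjusted over the list alone (camera adjusted p = 0.259); its mean was 0.18 and its median -0.01. With all 9 arrays 1 of 18, Crh, rose over all genes and adjusted over the list alone, and the list's mean and median (-0.02 and -0.18) had the opposite sign to its test (adjusted p = 0.799).

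The third comparison asked how far the female and male responses overlap. Without array 5, 321 probe sets passed as higher in both sets, where 33.1 were expected, and 139 as lower, where 24.5 were expected (1-sided Fisher's exact p = 3.5e-284 and p = 1.9e-73, over 20492 probe sets). Together these 460 ran from 173 to 548 as each of the 18 arrays was left out, with 210, 173 and 260 without control female replicates 1, 3 and 4 and 185, 208 and 278 without dehydrated female replicates 1, 2 and 4. Shared rises included Dpys, Tnfaip6, Crh, Giot1, Opn3, Th, Fos, Creb3l1, Kcnn3 and Slc12a1, and shared falls Igfbp5, Col1a2, Slc13a4 and Dbp. Col1a2 is one of the meninges markers, whose list camera called lower in both sets at its preset correlation. With those markers' mean as a covariate, 0 of 259 female falls and 266 of 2038 male falls passed. Of the rises 6 of 384 and 577 of 1808 passed. In females that covariate can hardly be told apart from dehydration. Whether less meningeal tissue in the dissections adds to the shared falls was not tested. Sppl2a, an intramembrane protease named after its values were seen, passed in opposite directions in 1 of its 3 probe sets, with 1.05 ± 0.24 in females and -0.30 ± 0.08 in males. The fold changes correlated across probe sets at a Pearson r of 0.54 and a Spearman correlation of 0.48, and 88.5% of the 3719 probe sets called in males had the same sign in females; probe sets are not independent replicates. With array 5 included, 1 probe set, that of Crh, was shared and r was 0.29.

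The fourth comparison tested whether the dehydration effect differed between the female and male sets, which also differ in extraction and labelling, so that sex and set of arrays cannot be told apart. By limma 0 of 21729 probe sets passed with all 19 arrays, 1707 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0933. Without array 5, 7 passed. Kif5c, a motor protein of axonal transport (1380172_at), differed by 1.14 ± 0.15 (SE; adjusted p = 0.00299), with 1.04 ± 0.12 in females (n = 4 each) and -0.11 ± 0.09 in males (n = 5 each). The other 6, named after their values were seen, included Igf1, insulin-like growth factor 1, with -0.20 ± 0.15 in females and -1.59 ± 0.17 in males, Wbp4, with 0.52 ± 0.14 and -0.54 ± 0.10, and Znf740, with -1.08 ± 0.20 and 0.31 ± 0.15. N4bp1, whose level in females was too low for the fit of the female set, differed by 1.75 ± 0.30, and probe sets 1383777_at and 1372392_at, which have no symbol, by -1.04 ± 0.18 and -0.86 ± 0.15. The count ran from 1 to 55 as each of the 18 arrays was left out.

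The difference between sets was tested for the 28 lists as well, and no call held with an estimated correlation. Without array 5, oligodendrocyte and myelin markers were lower in the female than in the male effect, with a mean difference of -0.43, with 0 of 15 members past limma's threshold, 6 at an unadjusted p under 0.05 and 3 adjusted over the list alone (adjusted p = 0.6 with an estimated correlation). The mural cell and meninges list differed the other way, by 0.38 (adjusted p = 0.661 with an estimated correlation), as did the ependyma and choroid plexus list, by 0.69 (adjusted p = 0.6 with an estimated correlation), and the ribosomal protein list, by 0.11 (adjusted p = 0.82 with an estimated correlation; under quantile normalization its mean was -0.133 in those females and -0.145 in males), with 0 members of these past limma's threshold over all genes or adjusted over the list alone and 1, 1 and 0 at an unadjusted p under 0.05. With all 19 arrays the meninges (0.62), microglia (0.49), ependyma (1.01) and endothelium (0.44) lists were higher in the female effect and the heat shock list lower (-0.26), with 0 members past limma's threshold over all genes or adjusted over the list alone and 2, 0, 2, 0 and 1 at an unadjusted p under 0.05 (adjusted p = 0.685 for the meninges, ependyma and heat shock lists, adjusted p = 0.694 for microglia and adjusted p = 0.737 for endothelium, with an estimated correlation). The first 4 are lists of markers that were higher on array 5. Without it the microglia (0.16), endothelium (0.05) and heat shock (-0.11) lists were not called (camera adjusted p = 0.221, adjusted p = 0.567 and adjusted p = 0.221).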

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

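The 4 tests of array 5, the count of meninges markers, the tests of array number, spread and fold size in the female set, and the setting aside of array 5 were chosen after the results they address were seen, though leaving out each array in turn was planned; the other splits and the remaining meninges tests were not. Chance alone makes about 1 in 20 groups hold a sample that stands apart by the gap rule used here, in which the gap to the nearest array is compared with the group's range.

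Array 5, labelled a dehydrated female, stood apart from its group in 12 array measures and in 51 named genes. Its median signal was 64.4, its median correlation with the female arrays 0.717, its Avp signal 50.6 and its Oxt signal 26.0, its Xist signal 2.59 and its Eif2s3y signal 242. The mean log2 value of its markers was the highest of its group for microglia (10.32), endothelium (11.56), meninges (10.99), blood (10.17) and ependyma and choroid plexus (10.22), and the lowest for magnocellular neurons (8.02). Among the genes with the largest excess on this array, named after their values were seen, were Ttr with 9458, Enpp2 with 8024, Mag with 1763 and Sostdc1 with 1306 (other females 673 ± 494, 567 ± 151, 126 ± 50.6 and 37.9 ± 8.78; SD, n = 8).

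For array 5, tissue mixed into a female supraoptic sample is argued against by Xist at 0.475% of the other females' mean, and a response to dehydration by the other 4 dehydrated arrays, whose Avp log2 change was 0.33 with a 95% interval from -0.14 to 0.80. Degraded RNA is argued against by a beta-actin 3' to 5' ratio of 3.06, inside the range of 2.44 to 13.3 of the other female arrays. All 7 probe sets of Xist, Eif2s3y and Uty lay nearer the male than the female mean, though the 2 of Uty read higher in females than in males (165 against 84.5 and 37.7 against 22.6) and so do not measure a Y-linked transcript; by the other 5, a candidate explanation is RNA of another sample under this label, from male tissue with few magnocellular neurons. No male array was out of place in turn, which a sample from outside these groups would not need. The sample title of array 5 carries a number outside the run of those of the other 4 dehydrated female arrays. Where the exchange took place, if there was one, is not shown by these values.

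In dehydrated males the meninges markers fell together, by a mean log2 change of -0.82. More 3' biased RNA is argued against as the whole cause, since with the beta-actin 3' to 5' ratio as a covariate the mean change was -1.06. Within the groups these markers varied together, at a median correlation of 0.909 against a 95th percentile of 0.307 in 10000 random lists of the same size and level, so a smaller share of meningeal tissue in the dehydrated dissections may contribute; among females without array 5 the value was 0.310 against 0.378. A lower expression within the same cells cannot be told apart from it, because each array holds whole dissections: 12 of 15 markers fell, which either would give. With the markers' mean as a covariate 266 of the 2038 male falls and 577 of the 1808 rises passed.

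Fewer probe sets passed in females without array 5 (643) than in males (3846), but not with all groups in 1 fit, which gives both sets the same residual SD (2322 against 2270). The number of arrays as the whole cause is argued against by the 25 male fits with 4 arrays per group that each leave out 1 array of each group, which called 2581 in the median and at least 2013. A wider spread between the female arrays is consistent with a median ratio of residual SD of 1.29, female over male (0.229 against 0.178). Smaller fold changes in females stay open: over 523 probe sets with adjusted p under 0.001 in males the slope of female on male changes was 0.89, with a jackknife 95% interval from 0.784 to 0.996, which lies below 1, but choosing by the male p favours large male changes. Sex, extraction and labelling differ together between the sets, and a biological difference between the sexes stays open as untested.

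For the count in males, 1 of 100 splits of the arrays, the real one, gave as many calls (3846, the highest other 649). For females without array 5 it was 1 of 35 (643, the highest other 0). Both shares lie under 5%, which argues against chance for both counts. In females 1 of 35 is the lowest share that the splits can give, and array 5 was set aside after the data were seen. With all 9 female arrays, 2 of 100 splits, the real one included, gave as many calls as the real one (1). The other of these 2 gave 56, many times the real count. How that split grouped the arrays was not examined, so its count stays unexplained. With a real count of 1 the splits say little. For the difference between sets with all arrays, 100 of 100 splits gave as many as the real 0 (the highest other 45), which a count of 0 fixes beforehand, so the splits decide nothing; limma's count at an unadjusted p under 0.05 was 1707. Without array 5, 3 of 100 splits gave as many as the real 7 (the highest other 19). These splits mix dehydrated with control arrays within each set, so the dehydration effect shared by the sets enters their residual spread. They therefore do not show what equal effects in both sets would give, and chance stays open for that count.

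Female and male dehydration effects differed by limma without array 5 for 7 probe sets: Kif5c by 1.14, Wbp4 by 1.06, N4bp1 by 1.75, Igf1 by 1.40, Znf740 by -1.39, 1383777_at by -1.04 and 1372392_at by -0.86, as female minus male log2 fold change.

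Control female replicate 2 stood apart in its beta-actin 3' to 5' ratio (13.3) and its Gapdh ratio (4.12), and dehydrated female replicate 4 in its beta-actin ratio (5.30). Named genes stood apart on control female replicate 2 in 8 checks, on control male replicate 1 in 6, on control male replicate 5 in 4 and on dehydrated male replicate 3 in 2. They did so in 1 check each on control female replicates 1 and 4, dehydrated female replicates 2 and 3, control male replicates 2 and 4, and dehydrated male replicates 1, 2, 4 and 5. In all, 81 of 496 checks of named genes (16.3%) met the rule, 51 of them on array 5.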

How the results depend on the processing

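Leaving out each array in turn, array 5 included, was planned. The choice of array 5 as the one to set aside, the alternatives run with it already left out, both covariates, the fit of all groups for females and median centring for the lists were chosen after the data were seen; the other alternatives were planned. No alternative was run for the lactating group, whose columns were empty, which also makes the planned fit of only the compared female groups identical to the one reported; the split of shared controls and the replicate block were not run. No paired analysis was possible because the replicate numbers mark no shared animal, batch or day. The cause was not tested for the changes below, except where fewer arrays or lists enter by construction.

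Female dehydration called 1 probe set, and 1 under quantile normalization, both offsets, both filters and no trend; it called 0 with arrays centred on their median (limma, 1708 at an unadjusted p under 0.05), 1603 with array weights, 553 with all groups in 1 fit, and 1 to 643 with each array left out. It was 643 without array 5, 2 without dehydrated replicate 4 and 1 without each of the others. Without array 5 the 643 calls became 1709 with array weights, 290 without the trend, 2322 with all groups in 1 fit, 1456 with the beta-actin ratio and 6 with the meninges score as a covariate, which raised the median SE of the 94 rises beyond 2-fold from 0.186 to 0.387 and of the 27 falls from 0.242 to 0.502, while their median log2 fold changes went from 1.23 to 1.57 and from -1.15 to -1.20. With each array left out they ran from 210 to 886 (210, 256 and 346 without control replicates 3, 1 and 4; 222, 246 and 334 without dehydrated replicates 1, 2 and 4). The other alternatives gave 462 to 729. The 3846 male calls became 427 with all groups in 1 fit (2270 with array 5 left out of it), 1540 with the beta-actin ratio and 989 with the meninges score; the range with each array left out was 2839 to 4149.

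The difference between sets called 0, with 1 under quantile normalization, 136 with array weights and 0 to 7 with each array left out (7 without array 5, 4 without dehydrated female replicate 3). Without array 5 the 7 calls became 18 under quantile normalization, 12 with median centring, 11 with an offset of 100, 2 without the filter and 114 with array weights, and ran from 1 to 55 with each array left out. Called lists fell to 1 of 6 in females, 2 of 16 in females without array 5 and 1 of 16 in males with an estimated correlation; with each array left out they ran from 5 to 16 in females, 14 to 16 without array 5 and 15 to 18 in males, and leaving out array 5 gave 16 in females. With fry, the mean over a gene's probe sets, quantile normalization or median centring 4 to 8, 13 to 17 and 13 to 20 were called. Of the lists reported as called, fry called 3 of 6, 14 of 16 and 15 of 16. The overlap of the sets went from 1 to 460 without array 5 (110 at a threshold of 0.01, 440 under quantile normalization), and the correlation from 0.295 to 0.537 (0.532 under quantile normalization). With each of the arrays left out the overlap ran from 1 to 460 and the correlation from 0.202 to 0.537; with array 5 already out they ran from 173 to 548 and from 0.505 to 0.543.

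Single genes that turned direction were mostly Avp, Oxt and the sex-linked genes, which passed no threshold. In females, Avp and Oxt went to 0.230 and 0.310 with array weights; with each array left out they ran from -1.44 to 0.33 and from -1.52 to 0.40, and Xist from -1.56 to 0.0143, the upper values being those without array 5. Without array 5, Xist went to -0.0490 under quantile normalization and to -0.0359 with array weights, and ran from -0.10 to 0.0924 with each array left out. In males, Uty went to 0.0172 under quantile normalization, to 0.0232 with median centring and to 0.0156 with the beta-actin ratio as a covariate, with which Camk2a went to 0.000973, Avp to -0.0615 and Oxt to -0.168. Oxt ran from -0.0323 to 0.0940 with each male array left out. With the meninges score as a covariate Igfbp2, itself one of its markers, went to 0.0512 and Rarres2 to 0.540 in females without array 5. In males Kdelr3 went to 0.0150, Lama2 to 0.135 and Vim to 0.0904 with that score. In the difference between sets, Avp, Oxt and Xist went to 0.145, 0.279 and 0.183 with array weights. With each array left out Avp ran from -1.52 to 0.25, Oxt from -1.54 to 0.38, Xist from -0.49 to 0.16 and Eif2s3y from -0.14 to 1.18. Without array 5, quantile normalization gave -0.00968 for Avp and -0.0255 for Xist, and with each array left out Xist ran from -0.11 to 0.21 and Eif2s3y from -0.32 to 0.0445.

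Of the named genes past the threshold in males, 47 lost their call with all groups in 1 fit (15 with array 5 left out of it), 40 with the meninges score, 23 with the beta-actin ratio, 13 without the trend, 10 with median centring, 9 without the filter, 7 under quantile normalization and 4 to 12 with each array left out. In females without array 5, 34 lost it with the meninges score, 14 without the trend, 10 without the filter, 7 with median centring and 3 to 15 with each array left out (15 without dehydrated replicate 2, 14 and 13 without control replicates 1 and 3). These counts leave out genes that turned direction, such as Kdelr3 and Vim in males and Igfbp2 in those females with the meninges score. Signal over background limits the lowest genes: among others, Dpys, Cdk1, Kcnn3, Slc12a1 and Giot1 had mean signals of 16.8, 17.5, 19.5, 27.4 and 28.1 in control females, and Cdk1, Cdkn3, Slc12a1, Kcnn3 and Giot1 of 16.1, 17.0, 18.7, 19.2 and 22.9 in control males, so by construction the size of their fold changes depends on the offset. Without array 5, Dpys rose by 4.59 with an offset of 1 and by 3.39 with an offset of 100, where Tnfaip6 rose more.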

Other observations

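The lists below were planned, and array 5 was set aside after the data were seen. Hormone receptor and prolactin signalling genes were not called as a list in males (camera adjusted p = 0.11), with 1 of 19 members higher and 5 lower over all genes, and 2 and 5 adjusted over the list alone. Prlr, the prolactin receptor, rose by 0.61 ± 0.12 (SE, n = 5 each), while Lepr, the leptin receptor, fell by 0.86 ± 0.16 and Nr3c2, the mineralocorticoid receptor, by 0.71 ± 0.13. Among females without array 5, 1 of 21 fell, Tsc22d3, a glucocorticoid-induced gene (-0.53 ± 0.11), and 3 adjusted over the list alone (camera adjusted p = 0.216). Of 30 GABA and glutamate receptor genes in males 1 rose, Grin1 (0.39 ± 0.05), and 2 fell, Gria2 (-0.35 ± 0.09) and Grm3 (-0.47 ± 0.13), over all genes and adjusted over the list alone (camera adjusted p = 0.769). Grm3 was also the 1 of 28 that fell in females without array 5 (-0.73 ± 0.17), with 2 adjusted over the list alone (camera adjusted p = 0.259). Of 33 genes of structural remodelling and matrix 4 rose and 6 fell in males, against 5 and 7 adjusted over the list alone (camera adjusted p = 0.604): the tubulins Tubb3 and Tubb2b rose by 0.58 ± 0.08 and 0.55 ± 0.06, and fibronectin, Fn1, fell by 0.77 ± 0.19, on the arrays where meninges markers fell. For those females limma called 0 of 34, with 2 higher and 3 lower at an unadjusted p under 0.05, and 2 and 2 adjusted over the list alone (camera adjusted p = 0.797).

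Glycolysis genes were not called as a list in males (camera adjusted p = 0.103, and adjusted p = 0.0314, a call, with arrays centred on their median; 4 of 18 higher, and 6 higher and 2 lower adjusted over the list alone) or in females without array 5 (camera adjusted p = 0.796; 1 of 19 higher and 1 lower, and 1 and 2 adjusted over the list alone). Ldha, lactate dehydrogenase A, rose in both sets, by 0.72 ± 0.07 in males (n = 5 each) and 0.80 ± 0.14 in females without array 5 (n = 4 each), and Pfkm, muscle phosphofructokinase, fell by 0.46 ± 0.11 in those females. Of 20 cell cycle genes in males 3 rose, among them Cdk1 (0.78 ± 0.16) and Cdkn3 (0.49 ± 0.15), and 1 adjusted over the list alone (camera adjusted p = 0.0987). Of 8 magnocellular neuron markers in males 2 rose, Calb2 by 0.78 ± 0.07 and Slc17a6, the vesicular glutamate transporter, by 0.58 ± 0.06, and 1 fell, Rbp4 (-0.98 ± 0.26), over all genes and adjusted over the list alone (camera adjusted p = 0.0612). Of 8 markers of other hypothalamic neurons in males Th rose by 1.51 ± 0.12 and Hcrt, the orexin precursor, fell by 0.87 ± 0.27, over all genes and adjusted over the list alone, and the list's mean of -0.09 had the opposite sign to its test (camera adjusted p = 0.869). Th rose in females without array 5 (1.98 ± 0.14) and Gnrh1 fell by 0.84 ± 0.19 among 7, over all genes and adjusted over the list alone (camera adjusted p = 0.388). Of 15 oligodendrocyte markers in males 1 fell, Aspa (-0.88 ± 0.25), over all genes and adjusted over the list alone (camera adjusted p = 0.261).

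Of further lists not called in males limma called 0 of 14 endothelium, 0 of 5 GABAergic and 0 of 3 cortical and amygdalar neuron markers (camera adjusted p = 0.769, adjusted p = 0.302 and adjusted p = 0.821), with 1 higher and 2 lower among the endothelium markers and 0 among the others at an unadjusted p under 0.05. Of those not called in females without array 5 it called 0 of 14 endothelium, 0 of 8 ependyma and choroid plexus and 0 of 5 cortical and amygdalar neuron markers and 0 of 31 ribosomal protein genes (camera adjusted p = 0.601, adjusted p = 0.67, adjusted p = 0.933 and adjusted p = 0.67; under quantile normalization the ribosomal protein list was called lower, with a mean of -0.133 and adjusted p = 0.0186), with 1 higher and 1 lower among the cortical markers and 0 among the others at an unadjusted p under 0.05. None of these had a member past the threshold adjusted over the list alone in the set named. The mean had the opposite sign to the test for the endothelium list in males (-0.01) and, in those females, for the structural remodelling (-0.01), heat shock (-0.002) and cortical and amygdalar neuron (0.04) lists. Of 19 heat shock genes in those females 1 rose, Hspb8 (0.49 ± 0.12), and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.743).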
